A study of Danio rerio with 64 samples.

How the data were processed

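Total RNA of whole zebrafish embryos was labelled with Cy3 and hybridised to 1-colour Agilent expression arrays, 8 arrays on each of 8 slides. RNA was prepared with Trizol and a column cleanup, per the labels' protocols. Spots were quantified with Agilent Feature Extraction 11.5.1.1, per the file headers, and the scanner files hold the brightness of each spot as a linear intensity, as deposited by the authors, not yet normalized between arrays. Each array has 62976 spots, of which 61657 are not controls; these measure 60022 probes, 55321 with an Ensembl transcript identifier and 4701 with a GENSCAN prediction, and 300 probes have more than 1 spot. The authors also deposited a table of processed values with 1 row per spot, on a log2 scale. Each of its 64 columns ranked the spots most like its own scanner file (Spearman correlations of 0.998 to 1), with slopes of 0.885 to 1.08 on log2 scanner signal and column medians of 8.98 to 9.20. How these deposited values were normalized is not given in the sources used here; R 3.3.1 is named in the submitters' processing notes.

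Groups were taken from the labels as concentration, exposure time and recovery. For the recovery samples the label fields differ on the end of exposure, and the description, which gives clean water from 72 hpf, was followed. The second array of a group differs in its title only by a suffix, which was read as naming the sample and not used to pair arrays. At 24 h array 1 of control and of 122.51 µmol/L lay on the same slide and array 2 of both on another, so a difference between replicates of these groups is also one between slides. The series' design text speaks of embryos per replicate kept in vials, but the labels do not state that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 arrays of a group held identical values: they had no probe value in common in any of the 23 groups with 2 arrays.

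The main values were log2 gProcessedSignal minus each array's 75th percentile over non-control spots. Control spots and spots marked as outliers (19 to 985 per array) were left out, spots of a probe were averaged, and 3641 probe values were missing as a result. A probe was tested if it was well above background on both arrays of at least 1 group, which kept 59659 probes (54960 Ensembl transcripts and 4699 GENSCAN predictions). A mean was fitted per group over all 64 arrays, leaving 23 residual degrees of freedom, and tested with limma 3.58.1 in R 4.3.3 (moderated variances, prior degrees of freedom of 3.29, two-sided tests). The Benjamini-Hochberg adjustment ran over all features within a comparison, with a threshold of 0.05. The median residual SD was 0.23 on the log2 scale. The contrasts were 122.51 µmol/L against control at each time, averaged over times and differing between times (F test), the other concentrations against control at 48 and 72 h, the linear slope on concentration within each time (expressed as the change from 0 to 122.51 µmol/L), and recovery at 122.51 µmol/L against the 72 h controls and against continuous exposure at 72 h. Groups with 1 array enter only the slopes and the values. Number of arrays, not depth, limits the precision of array values, and with 2 arrays per group the test relies on the spread shared over groups.

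The group-mean fit was computed in closed form and checked against limma, from which its statistics differed by less than 1e-06. It was also tested on simulated data for the comparison of 122.51 µmol/L with control at 72 h over 59659 features. The simulation took the real group means and 1 spread per feature. Of 100 features changed by 1 log2 unit 45% were recovered, of 100 changed by 2 log2 units 92%, and 8 unchanged features were called. The simulated noise was independent between arrays and alike in all groups, unlike the real arrays. It checks the calculation and does not measure false calls in these data.

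None of the 60022 probe identifiers matched the gene tables used here, so no gene is named, and each probe is its own feature. Several transcripts can belong to 1 gene, so counts of features are not counts of genes. The 35 gene lists fixed beforehand, among them targets of the aryl hydrocarbon receptor and the prostanoid pathway, were not tested for the same reason. The rule for naming, fixed earlier, took features past the threshold with the largest rise or fall for which both exposed arrays lay on the same side of both controls. It asked for named genes, and was applied here to transcript identifiers, to the average over times (with the condition required at all 6 times) and to 2 features per direction. The comparisons, tests, naming rule and most alternatives were chosen before the data were examined. The alternatives were normexp background correction with an offset of 50 and quantile normalization, the deposited values, no filter on dim probes, a filter asking for 32 arrays well above background, the slide as a random block (duplicateCorrelation, consensus correlation of 0.410 within a slide) or as a fixed block, only the arrays of 1 time in the fit, log2 concentration over exposed arrays, and each array left out in turn. The normexp correction used gMedianSignal, the spot signal the files hold, in place of the mean signal planned.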

Results

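Whole zebrafish embryos (Danio rerio) were exposed to a mixture of 3 compounds, the herbicide diuron and the anti-inflammatory drugs diclofenac and naproxen, and total RNA was hybridised to 64 Cy3-labelled Agilent arrays. Exposure began at 24 hours post fertilisation (hpf), and embryos were sampled after 3, 6, 12, 24, 48 and 72 h, at 27, 30, 36, 48, 72 and 96 hpf. The mixture was given at 43.1, 61.06, 86.49, 102.93 and 122.51 µmol/L beside an unexposed control, concentrations that the series' design text anchors to modelled lethality at 96 hpf. A recovery series was exposed at the same 5 concentrations until 72 hpf and kept in clean water until 96 hpf. The 41 groups comprised 23 with 2 arrays and 18 with 1 array. Control and 122.51 µmol/L had 2 arrays at every time, all concentrations had 2 arrays at 48 and 72 h, and 86.49 and 102.93 µmol/L also had 2 at 24 h. At 3, 6 and 12 h the 4 lower concentrations had 1 array each, as had 43.1 and 61.06 µmol/L at 24 h and the 4 lower recovery concentrations. Between 93.2% and 99.6% of the non-control spots of an array were well above background, and none was saturated. A feature here is a probe for 1 Ensembl transcript or 1 GENSCAN gene prediction, and 59659 features were tested. The files do not pair these identifiers with gene names, so 2 transcripts that rose and 2 that fell are followed by identifier.

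**Figure D1:**
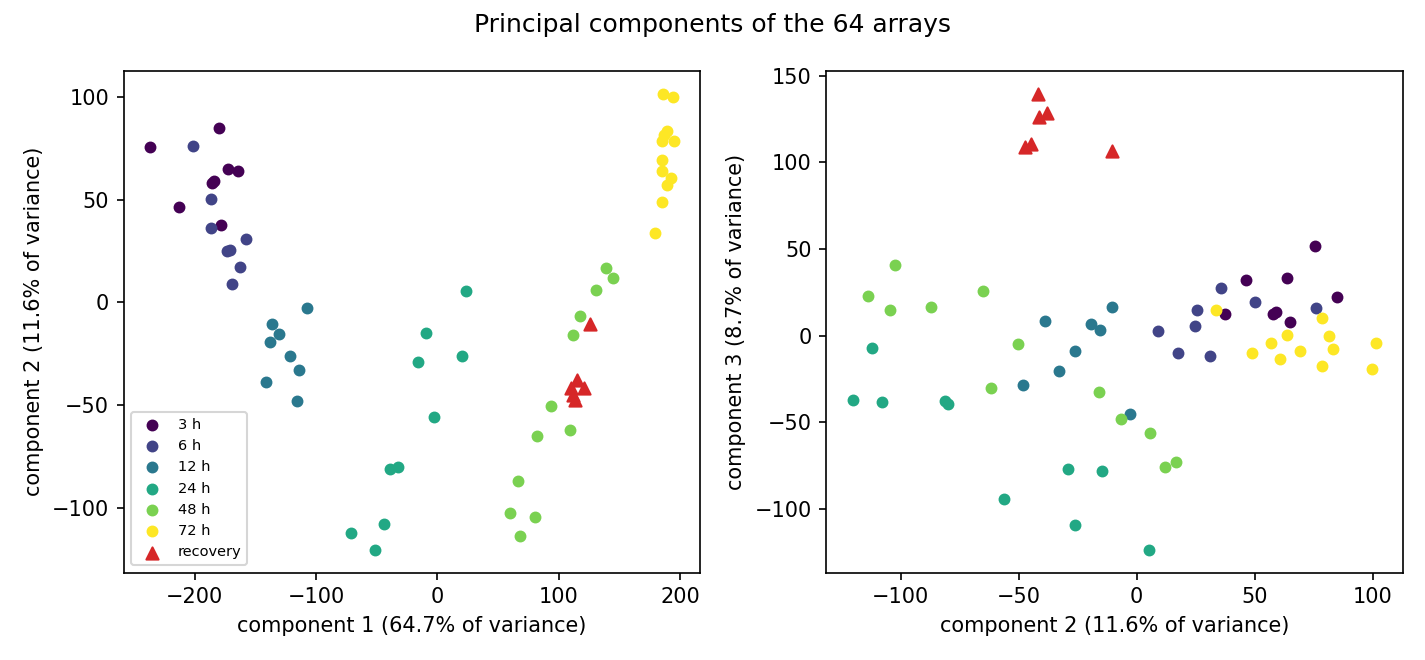
First 3 principal components of the 64 arrays, computed on log2 signal minus each array's 75th percentile; each point is an array, coloured by hours of exposure, and triangles are the 6 recovery arrays. Along component 1 (64.7% of the variance) the 3 and 6 h arrays overlap and those of 12, 24, 48 and 72 h follow in order, the arrays of 24 and 48 h spread along component 2, and the recovery arrays lie apart from the 72 h arrays, within the range of the 48 h arrays on component 1 and above all other arrays on component 3.

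Most of the difference between arrays went with exposure time. On the first principal component, with 64.7% of the variance, the arrays of 3 and 6 h overlapped and those of 12, 24, 48 and 72 h followed in order. The recovery arrays, of 96 hpf, had scores of 110 to 126, within the 60 to 145 of the 48 h arrays and below the 179 to 195 of the 72 h arrays. On the third component (8.66% of the variance) they scored 107 to 140, against -75.8 to 40.8 for the 48 h arrays. In unexposed embryos 355 features changed between 3 and 6 h (limma, Benjamini-Hochberg adjusted p under 0.05), 5482 between 6 and 12 h, 9352 between 12 and 24 h, 13513 between 24 and 48 h and 8766 between 48 and 72 h. The controls of each time lay on other slides than those of the other times, so these counts also hold any difference between slides. Replicate arrays of 1 group correlated across features at Pearson r of 0.951 to 0.997. The spread within groups was uneven: the SD of the difference between the 2 control arrays was 0.85 on the log2 scale at 24 h and 0.53 at 48 h, against 0.20 at 72 h. The 2 control arrays of 24 h lay on different slides, as did the 2 of 122.51 µmol/L, while those of 48 h lay on 1 slide. At 24 h the 2 arrays of 86.49 µmol/L also lay on 1 slide, as did the 2 of 102.93 µmol/L. Their differences had SDs of 0.51 and 0.63, against 0.68 for 122.51 µmol/L, so a wide spread also arose within 1 slide. The exposed groups of 48 h, each on 1 slide, had SDs of 0.56 to 0.77. All groups shared 1 estimate of the spread, so that the quiet groups of 72 h were judged against the noisier ones of 24 and 48 h. The groups of 24 and 48 h were in turn judged against a spread lowered by the quieter groups, so their p-values may be too small.

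The response to the highest concentration was followed through the 6 exposure times. Transcript ENSDART00000038200 was higher at 122.51 µmol/L at every time. It lay 3.93 ± 0.31 log2 units above control after 3 h (15.2-fold, estimate ± SE, n = 2 against 2, limma adjusted p = 8.69e-08), 2.92 ± 0.31 after 6 h, 3.87 ± 0.31 after 12 h, 4.93 ± 0.31 after 24 h (30.6-fold, adjusted p = 4.38e-10), 4.16 ± 0.31 after 48 h and 3.02 ± 0.31 after 72 h (8.11-fold, adjusted p = 4.01e-07). In the 2 control arrays of 24 h its level was -1.09 ± 0.15 (mean ± SD of log2 signal relative to the 75th percentile), and in the exposed arrays 3.84 ± 0.13. The SE of each estimate comes from the spread shared over groups, not from the arrays of that time. Its 2 exposed arrays of 6 h lay at 1.47 and 2.89. Transcript ENSDART00000019953 was not past the threshold at 3 h, where it lay 0.51 ± 0.26 above control (adjusted p = 1). It rose by 1.24 ± 0.26 at 6 h (adjusted p = 0.021), 2.35 ± 0.26 at 12 h, 2.54 ± 0.26 at 24 h (5.80-fold, adjusted p = 2.68e-06), 1.87 ± 0.26 at 48 h and 1.69 ± 0.26 at 72 h. The 6 h call of ENSDART00000019953 was lost without exposed array 2 (adjusted p = 0.183), without control array 1 (adjusted p = 0.421) and after normexp and quantile normalization, where the difference was 0.66 (adjusted p = 0.201). With only the arrays of the same time in the fit, the 6 h calls of ENSDART00000038200 (adjusted p = 0.827) and ENSDART00000019953 (adjusted p = 0.887) and the 24 h call of ENSDART00000019953 (adjusted p = 0.166) were lost at unchanged estimates. Transcript ENSDART00000087241 fell by 1.66 ± 0.22 at 72 h (3.16-fold lower, adjusted p = 1.52e-05), from -0.88 ± 0.01 in controls to -2.54 ± 0.37, and its difference was -0.67 ± 0.22 at 48 h (adjusted p = 0.175). Transcript ENSDART00000118248 passed the threshold at none of the 6 times taken alone, with differences from -0.90 to -0.20.

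**Figure D2:**
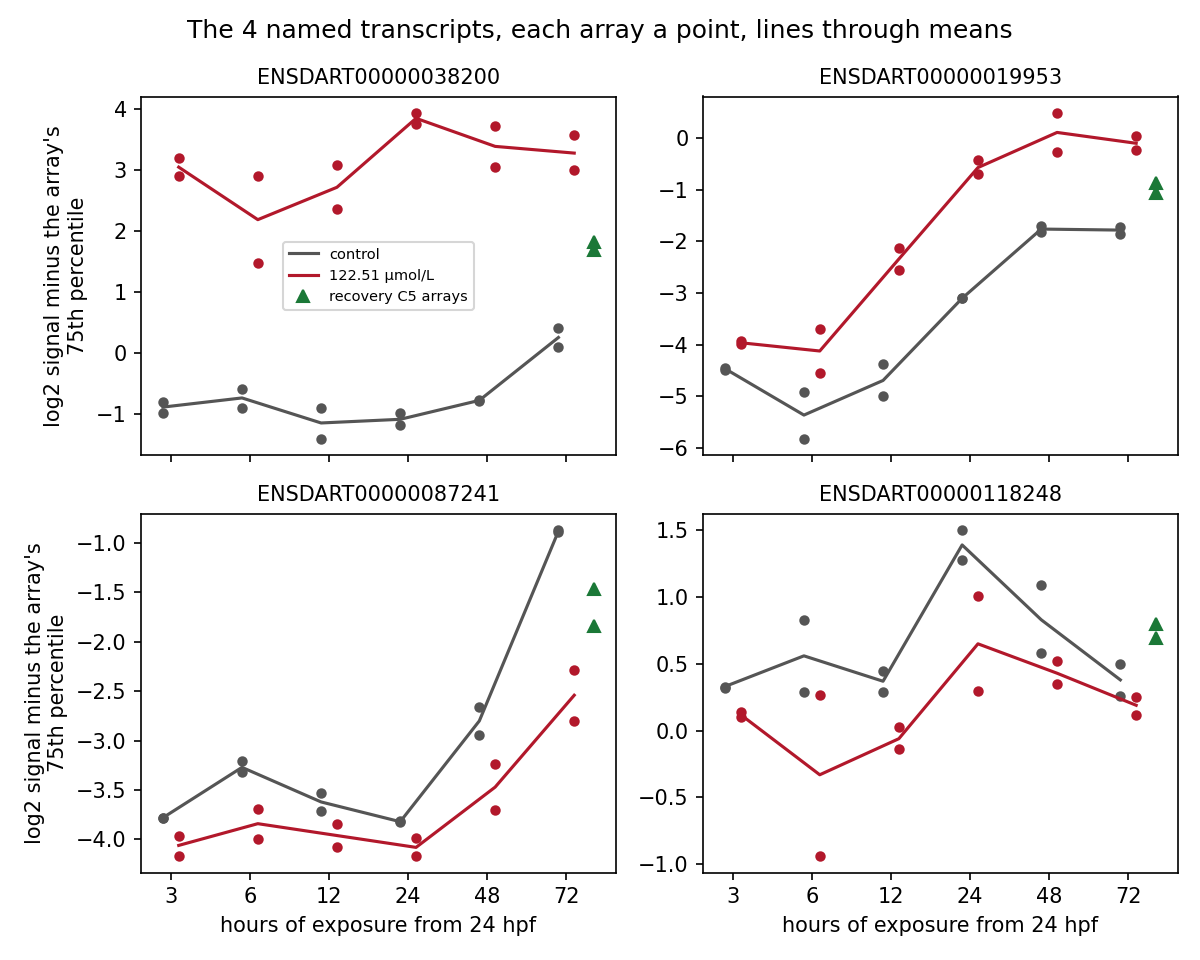
Log2 signal relative to each array's 75th percentile for the 4 named transcripts against hours of exposure, in control (grey) and at 122.51 µmol/L (red); points are single arrays, lines join the means of 2 arrays, and green triangles are the recovery arrays of 122.51 µmol/L at 96 hpf. ENSDART00000038200 lies 2.92 to 4.93 above control at all 6 times and 1.5 above control in recovery.

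The number of features changed at 122.51 µmol/L did not follow the length of exposure. After 3 h 5 features passed the threshold, of which 4 rose, and 1572 had an unadjusted p under 0.05. After 6 h 529 changed, 81 upwards and 448 downwards. After 12 h 5509 changed, 1315 upwards and 4194 downwards, of which 1657 moved by more than 1 log2 unit (81 upwards and 1576 downwards). After 24 h 67 changed, 55 of them upwards. After 48 h 844 changed, 489 upwards and 355 downwards, and the largest rise was 5.29. After 72 h 3576 changed, 1129 upwards and 2447 downwards, with a median size of 0.80 among them, a largest rise of 5.19 and a largest fall of -5.09. The share of falls at 12 h was 76.1% with the 75th-percentile scaling, 49.6% after normexp and quantile normalization and 42.8% in the deposited values, and at 3 h it was 20.0% (1 of 5 features) against 33.3% in the deposited values. At 48 h rises outnumbered falls only with the 75th-percentile scaling. The share of falls was 42.1%, against 51.8% after quantile normalization and 51.9% in the deposited values.

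Counts at 2 against 2 arrays moved widely when 1 array was left out. At 12 h the count was far lower without control array 1 or exposed array 1, lower without exposed array 2 and higher without control array 2. At 6 h leaving out any of the 4 arrays gave from 35 to 1968 features (46 and 35 without control array 1 or 2, 1923 and 1968 without exposed array 1 or 2). At 3 h the count was 28 without control array 1 and 11 without control array 2, and at 24 h it was 39 without control array 1 and 38 without exposed array 2. At 48 h it was 437, 468 and 362 without exposed array 1, control array 1 and control array 2. At 72 h it was 2026, 1561 and 1477 without exposed array 2, control array 1 and control array 2. With only the arrays of the same time in the fit, 72 h gave 11253 features and 12 h 555, while 48 h gave 118, 24 h gave 1 and 6 h gave 0 (limma, 3131 of the tested features at an unadjusted p under 0.05).

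**Figure D3:**
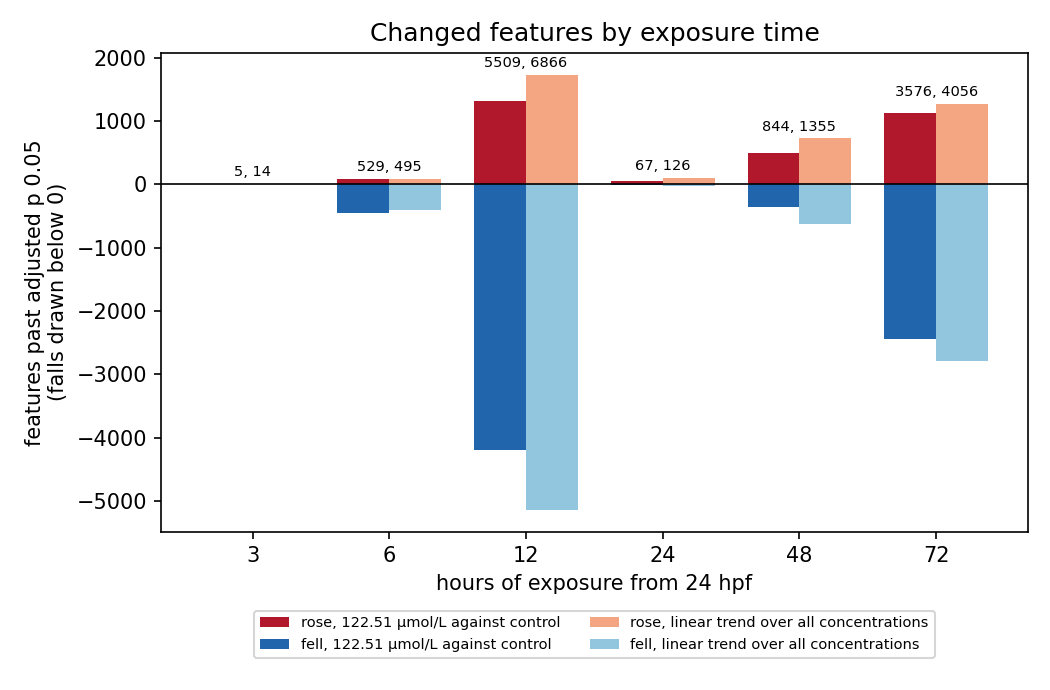
Number of features past a limma adjusted p of 0.05 against hours of exposure, for 122.51 µmol/L against control (dark bars) and for the linear trend over all concentrations (light bars); rises are drawn above 0 and falls below it, and the paired figures give both totals. The bars are longest at 12 h (5509 and 6866 features) and at 72 h (3576 and 4056).

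The features changed after 48 and after 72 h overlapped beyond independent lists, on separate arrays. Each feature had 1 spread for both times, which by itself can bring the lists closer than independent ones. Of the 844 features of 48 h and the 3576 of 72 h, 320 rose at both times and 259 fell at both, where independent lists would share 9.25 and 14.6, and 5 changed in opposite directions. Fewer features changed the same way at both times when exposed array 1, control array 1 or control array 2 of 48 h was left out. Across features, which are not independent replicates, the effects of 48 and 72 h correlated at Pearson r of 0.53. Between 24 and 48 h 33 features rose at both times and 7 fell at both, against 0.451 and 0.0714 for independent lists. Between 12 and 72 h the shared features were as often opposed as alike: 145 changed the same way and 160 the opposite way, against 197 and 133 for independent lists, and r was -0.09. The effect of 122.51 µmol/L differed between times for 2616 features by an interaction test (limma F test, adjusted p under 0.05). The 3 named transcripts ENSDART00000038200 (adjusted p = 0.034), ENSDART00000019953 (adjusted p = 0.00709) and ENSDART00000087241 (adjusted p = 0.0301) were among them, and ENSDART00000118248 was not (adjusted p = 0.809). The interaction count was 1457 and 1490 without control array 2 or 1 of 72 h, 1470 without exposed array 1 of 12 h, 4544 without exposed array 1 of 24 h and 4805 without exposed array 2 of 6 h.

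Averaged over the 6 times, 2196 features differed between 122.51 µmol/L and control, 936 upwards and 1260 downwards, and 34 of them by more than 1 log2 unit (31 upwards). ENSDART00000038200 led the rises with 3.81 ± 0.13 (14.0-fold, n = 12 against 12, limma adjusted p = 5.92e-17), and ENSDART00000019953 rose by 1.70 ± 0.11 (adjusted p = 5.03e-11). ENSDART00000087241 fell by 0.63 ± 0.09 (adjusted p = 6.13e-05) and ENSDART00000118248 fell by 0.48 ± 0.12 (adjusted p = 0.0236). In these 4 transcripts both exposed arrays lay on the same side of both control arrays at all 6 times, as in 32 of the 2196 features (23 that rose and 9 that fell). The share of falls was 57.4%, against 47.2% after quantile normalization and 46.2% in the deposited values. The count was 1393 without control array 1 of 6 h, 3825 without control array 2 of 12 h and 5205 without exposed array 1 of 24 h. The call of ENSDART00000118248 was lost, with adjusted p up to 0.0655, when any of 6 arrays was left out.

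The concentration series was tested for a linear slope on concentration, with control as 0. A step from control to all concentrations can also give such a slope, so the counts are not of changes in proportion to concentration. At 72 h 4056 features had a slope past the threshold (1270 upwards, 2786 downwards), at 48 h 1355 (729 and 626), at 24 h 126 (103 and 23), at 12 h 6866 (1730 and 5136), at 6 h 495 (90 and 405) and at 3 h 14 (12 and 2). Most of the rise of ENSDART00000038200 was already present at the lowest concentration at 48 and 72 h. At 48 h it stood 3.3 ± 0.31 above control at 43.1 µmol/L, 3.88 at 61.06, 4.03 at 86.49, 4.31 at 102.93 and 4.16 at 122.51 µmol/L, and at 72 h 3.56 ± 0.31 at 43.1 µmol/L (11.8-fold, limma adjusted p = 1.59e-07) against 3.02 at 122.51 µmol/L. At 12 h, with 1 array per lower concentration, its difference grew from 2.16 at 43.1 µmol/L over 2.75, 3.34 and 4.18 to 3.87 at 122.51 µmol/L. ENSDART00000019953 at 24 h stood 1.2, 1.48, 2.13, 2.37 and 2.54 above control in order of concentration, the first 2 from 1 array each. At 72 h it did not follow that order, with 2.24, 1.27, 1.85, 2.08 and 1.69. ENSDART00000087241 at 72 h fell by 1.24 ± 0.22 at 43.1 µmol/L (adjusted p = 0.00591), by 1.25 at 61.06, 1.27 at 86.49, 1.4 at 102.93 and 1.66 at 122.51 µmol/L. The 43.1 and 61.06 µmol/L arrays of 72 h lay on another slide than the controls, and with the slide as a random block these calls of ENSDART00000087241 were lost (adjusted p = 0.961 and 0.622) at unchanged estimates of -1.24 and -1.25, since only the precision fell. At 43.1 µmol/L its call was also lost without any 1 of the 4 arrays, with adjusted p of 0.0585 to 0.19. It was lost at 61.06 µmol/L without control array 1 or 2 or exposed array 1 (adjusted p = 0.067, 0.0666 and 0.0768) and at 86.49 µmol/L without exposed array 2 (adjusted p = 0.0996). The share of falls at 12 h was 74.8%, against 47.1% after quantile normalization and 41.9% in the deposited values, and at 48 h 46.2% against 64.3% and 64.9%. With the slide as a fixed block, fitted to the arrays of that time alone, the slope count was 18 at 24 h, 337 at 48 h and 7511 at 72 h. Log2 concentration over exposed arrays gave 3164 at 3 h and 312 at 12 h. The only array of 43.1 µmol/L at 3 h had the most outlier spots of all arrays (985) and the lowest share well above background (93.2%). Whether the 3164 features rest on this array was not tested. Single arrays moved the slope counts too. Without control array 1 or 2 the count was 145 and 41 at 3 h and 175 and 168 at 6 h, and without array 1 or 2 of 122.51 µmol/L it was 88 and 2064 at 6 h and 2352 and 2604 at 72 h. At 3 h it was 7 without the array of 86.49 µmol/L and 28 without array 2 of 122.51 µmol/L. At 12 h it was 43 without control array 1 and 2201 without array 1 of 122.51 µmol/L, and without control array 2 it was 79 at 24 h and 730 at 48 h.

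Single concentrations could be tested against control at 48 and 72 h. The number of changed features grew with concentration at 72 h, and at 48 h up to 102.93 µmol/L: at 48 h 86, 148, 361, 1119 and 844 from 43.1 to 122.51 µmol/L, and at 72 h 209, 278, 493, 978 and 3576. The arrays of 43.1, 61.06 and 86.49 µmol/L at 48 h, and of 43.1 and 61.06 µmol/L at 72 h, were on other slides than their controls. With the slide as a random block their counts were 10, 18, 62, 14 and 23, while 102.93 and 122.51 µmol/L kept counts within 1.5 times. At 102.93 µmol/L and 48 h, where 922 features rose and 197 fell, the count was 198 and 335 without control array 1 or 2, and 283 and 3598 without exposed array 1 or 2. Without control array 1 the counts of the 3 lower concentrations at 48 h were 25, 47 and 189, and those of the 4 lower concentrations at 72 h 56, 90, 172 and 396. Without exposed array 1 or 2 they were 45 and 32, 40 and 60, and 446 and 126 at 48 h, and 33 and 70, 136 and 195, 201 and 122, and 537 and 363 at 72 h. The share of falls depended on the scaling at 61.06, 86.49 and 102.93 µmol/L at 48 h (29.1%, 51.5% and 17.6%, against 48.1%, 69.4% and 35.0% after quantile normalization and 39.2%, 62.6% and 42.7% in the deposited values). It also did so at 43.1 and 61.06 µmol/L at 72 h (41.1% and 29.9%, against 67.2% and 47.2%, and 58.5% and 40.1%).

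The features called at 48 h were followed on the 72 h arrays, which entered their choice only through the shared spread. The 489 features that rose at 48 h lay at a median of 0.24 above the 72 h controls at 43.1 µmol/L, 0.35 at 61.06, 0.38 at 86.49, 0.73 at 102.93 and 0.95 at 122.51 µmol/L, and 94.9% of them were above control at 122.51 µmol/L. The 355 features that fell at 48 h lay at -0.20, -0.20, -0.42, -0.53 and -0.80 in the same order, with array medians of -0.77 and -0.82 at 122.51 µmol/L. In the other direction, the 1129 features that rose at 72 h had medians of 0.14, 0.10, 0.18, 0.34 and 0.48 on the 48 h arrays, and the 2447 that fell at 72 h had -0.04, -0.13, -0.28, -0.15 and -0.35.

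**Figure D4:**
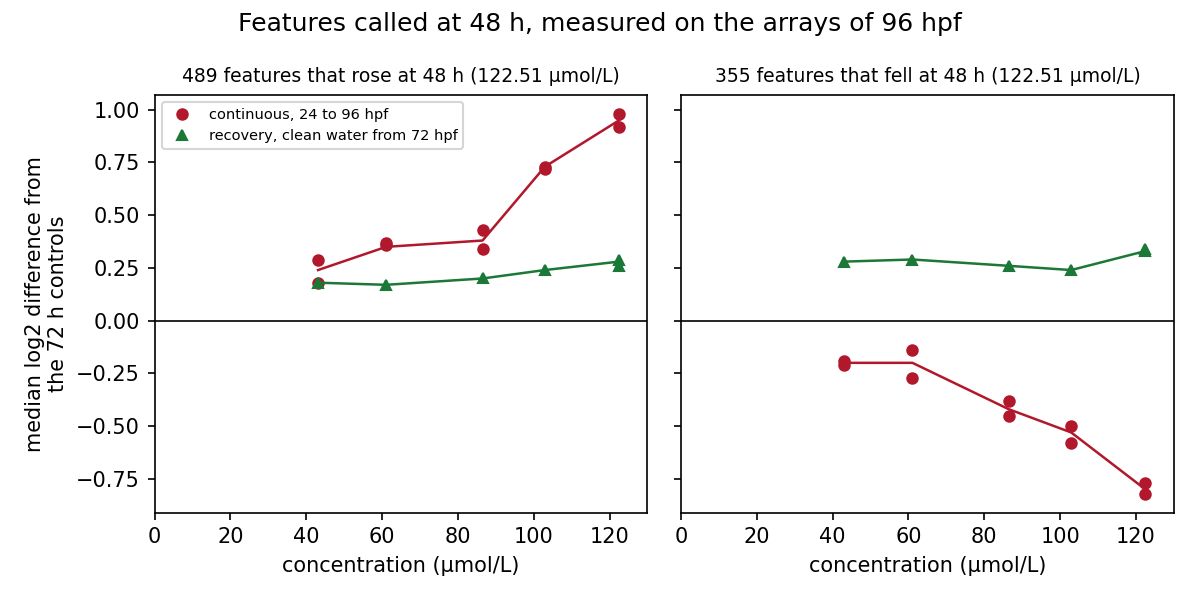
Median log2 difference from the 72 h controls, against concentration in µmol/L, of the 489 features that rose (left) and the 355 that fell (right) at 48 h and 122.51 µmol/L; points are single arrays and lines join group values for embryos exposed until 96 hpf (red circles) and embryos moved to clean water at 72 hpf (green triangles). The continuous series runs from 0.24 to 0.95 and from -0.20 to -0.80, and the recovery series from 0.18 to 0.28 and from 0.28 to 0.33.

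The recovery series asked what remained 24 h after the end of exposure. ENSDART00000038200 stood 1.5 ± 0.31 above the 72 h controls in the recovery arrays of 122.51 µmol/L (2.82-fold, n = 2 against 2, limma adjusted p = 0.00766) and 1.52 ± 0.31 below the continuously exposed arrays (log2 change of -1.52, adjusted p = 0.000896). In the single recovery arrays of the lower concentrations it lay 0.56, 0.80, 1.07 and 0.90 above control. ENSDART00000019953 stood 0.82 ± 0.26 above control in recovery (adjusted p = 0.0482) and ENSDART00000087241 fell by 0.77 ± 0.22 (adjusted p = 0.0339), while ENSDART00000118248 differed by 0.36 ± 0.30 (adjusted p = 0.399). Without recovery array 1 or 2, or control array 2, the call of ENSDART00000038200 against control missed the threshold (adjusted p = 0.0654, 0.0807 and 0.132), and those of the other 2 were lost without any 1 of the 4 arrays. With the slide as a random block no recovery call of these transcripts remained: adjusted p was 0.426 for each of the 3 against control, and 0.0603 for ENSDART00000038200 against continuous exposure. There the estimates were unchanged (1.5, 0.82 and -0.77 against control, and -1.52) and only their precision fell. A fixed block, which assumes a linear relation to concentration, gave -0.32 for ENSDART00000038200, -0.16 for ENSDART00000019953 and -0.23 for ENSDART00000087241 against control. None of these passed the threshold. At 72 h the 3 transcripts did not follow such a line: ENSDART00000038200 stood 3.56 above control at 43.1 and 3.02 at 122.51 µmol/L. The slide term also takes up this departure, so the fixed-block values cannot tell what remained in recovery. Of the 489 features that rose at 48 h, 308 were lower in recovery than under continuous exposure at 122.51 µmol/L and 11 were higher. Of the 355 that fell at 48 h, 322 were higher in recovery and 1 was lower. Over all tested features 14269 were higher and 10381 lower in recovery, 41.3% in all. The list that fell also lay above control in recovery at 43.1 µmol/L, so its count does not by itself show an effect undone. The medians of both lists hardly changed with concentration in recovery, from 0.18 at 43.1 to 0.28 at 122.51 µmol/L and from 0.28 to 0.33, under all 3 scalings.

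Across all features the recovery arrays of 122.51 µmol/L differed from control in 5748 features (2569 upwards, 3179 downwards) and from continuous exposure in 24650 (14269 upwards, 10381 downwards), and the median of all features shifted by 0.14 in the second comparison (0.20 in the deposited values). Among changes of more than 1 log2 unit falls led in both comparisons. Against control 476 rose and 2418 fell, and against continuous exposure 2564 rose and 6507 fell. The share of falls among all calls against control was 55.3%, and 44.9% in the deposited values. These differences ran along a direction that also separated replicate arrays. Across features the recovery minus continuous difference had an absolute Pearson r of 0.83 with the difference between the 2 control arrays of 48 h. The absolute r was 0.80 with that between the 2 control arrays of 24 h, which lay on different slides, against 0.19 for those of 72 h. At 43.1 µmol/L, where recovery and continuous arrays are all different ones, these values were 0.85 and 0.77. The recovery arrays of 122.51 µmol/L shared no slide with the 72 h controls or the continuous arrays of that concentration. With the slide as a random block 58 features differed from control and 3029 from continuous exposure. As a fixed block, fitted only to the 72 h arrays and these recovery arrays, 25626 and 32089 differed. On the only slide with both, the 4 recovery arrays of 86.49 to 122.51 µmol/L differed from the 4 continuous arrays of 43.1 and 61.06 µmol/L in 19840 features. Leaving out any of the 4 arrays gave from 262 to 781 features against control (470 and 297 without control array 1 or 2, 781 and 262 without recovery array 1 or 2) and from 9387 to 14994 against continuous exposure (13804 and 13395 without continuous array 1 or 2, 14994 and 9387 without recovery array 1 or 2).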

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

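The tests of slower development at 72 h, of the slide in the recovery comparison and of regrouped samples were fixed before their results were seen; the tests on the direction that separates replicates, on clean water, on slower development in recovery, on regroupings that keep slides, on single arrays and on scaling were chosen only after the results were seen. No group has the 4 arrays that a search for outlying arrays needs.

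A difference between times brought up 2616 features whose effect of 122.51 µmol/L was not the same at the 6 times by the limma F test. Among the transcripts named, the effect of ENSDART00000038200 spanned 2.01 log2 units between its lowest and highest time, that of ENSDART00000019953 2.03 and that of ENSDART00000087241 1.4. Of the 2616 features, 240 changed in both directions at different times, and 1268 had their largest effect at 72 h. When control and exposed labels were regrouped within times, 16 of 100 regroupings, the real one included, gave as many features, and the highest other gave 20490, so chance is not excluded for this count; with 1 array per slide kept in each arm at 24 h, 3 of 100 gave as many, and the highest other gave 5187. Why some regroupings called several times the real count was not tested. A structure of the samples within times may do so, and so may swapped labels of whole times, which turn a shared effect into a difference between times. For the average over times, 4 of 100 regroupings, the real one included, gave as many as the 2196 features, and the highest other gave 5539. With the slides kept in that way, 3 of 100 gave as many, and the highest other gave 7675. These shares lie under 0.05, but 100 drawn regroupings cannot settle a share so near that bound, so chance is not firmly excluded.

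The recovery arrays of 122.51 µmol/L differed from continuous exposure in 24650 features. A slide effect was tested first. With the slide as a fixed block, estimated from the continuous arrays, 32089 features were called, and as a random block 3029. The fixed block assumes a linear relation to concentration. Its fit held only the 72 h arrays and the recovery arrays of 122.51 µmol/L, so its spread is not the one behind the 24650. Using only the 72 h arrays, without a slide term, already raised the count for 122.51 µmol/L against control from 3576 to 11253. The fixed-block count therefore cannot decide on the slide. On the 1 slide with both series, at different concentrations, 19840 features still differed. If clean water undoing the exposure were the whole cause, the difference would be small at 43.1 µmol/L, where 209 features had changed, but its SD across features was 0.76, against 0.89 at 122.51 µmol/L, and the 2 differences, with no array in common, correlated at 0.85. The absolute correlation with the differences between replicate controls of 24 and 48 h averaged 0.82, consistent with 1 source that sets both the recovery arrays and some replicates apart; the 24 h pair lay on different slides, but the 48 h pair, on 1 slide, alone took up 68.5% of the variance of the recovery difference, and 69.1% with the change of controls from 48 to 72 h added. Slower development of the recovery embryos was not excluded: the recovery difference correlated at -0.48 with that change of controls, at -0.16 and -0.65 with array 1 or 2 of the 48 h controls alone, and that change itself correlated at 0.49 with the difference between these 2 arrays, so that development and this direction cannot be told apart, while handling or another batch remains possible and untested.

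The count of 5509 features at 12 h stands between 529 at 6 h and 67 at 24 h. The excess of falls over rises may come from the scaling of the arrays, because the share of falls, 76.1%, was at most 49.6% under either other scaling. Without control array 1 the count was 26, against 6962 without control array 2, which might point to that array, but it was also 52 without exposed array 1, so a single control array and a shared but weak change cannot be told apart with 2 arrays a side. Whether embryos at 36 hpf respond more widely than at 48 hpf therefore stays open.

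The 3576 features changed at 72 h were tested against a delay of development. The effect did not run against the change of the controls from 48 to 72 h. With 1 control array in the effect and the other in the change, Pearson r across features was 0.03, the mean of 0.04 and 0.03. That change, between arrays on different slides, itself correlated at 0.49 with the difference between the 48 h control arrays. It may therefore not hold development alone, so this r cannot decide on slower development. The direction that separates replicate controls of 24 and 48 h correlated with the 72 h effect at an absolute 0.21 on average, just above the bound of 0.2 set for excluding it, so a part in the 72 h effect could remain. A direct effect of the mixture stays open as a hypothesis, as does slower development.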

How the results depend on the processing

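The removal of the first residual component, the leaving out of 24 and 48 h and 3 counts (features shared by 48 and 72 h, and slopes on log2 concentration in recovery or differing from continuous exposure) were chosen after seeing the data. Counts stayed within 1.5 times of the main count with no dim filter and with the filter of 32 arrays, for all results. Where counts moved further, the cause was not tested unless stated. After normexp and quantile normalization the counts were 226 at 6 h and 2256 at 12 h for 122.51 µmol/L, 7, 209 and 3529 for the trends of 3, 6 and 12 h, 231 and 657 for 61.06 and 86.49 µmol/L at 48 h, 400, 527 and 751 for 43.1, 61.06 and 86.49 µmol/L at 72 h, 10348 for recovery against control and 297 for the difference of slopes (main count 146). The deposited values gave 3625 for 122.51 µmol/L at 12 h and 700 for 102.93 µmol/L at 48 h. The slide as a random block gave 10, 18 and 62 for 43.1, 61.06 and 86.49 µmol/L at 48 h, 14 and 23 for 43.1 and 61.06 µmol/L at 72 h, 2621 for the trend at 72 h, 58 for recovery against control and 3029 against continuous exposure. As a fixed block it gave 18, 337 and 7511 for the trends of 24, 48 and 72 h and 25626 for recovery against control. These fixed-block fits held only the arrays of that time, with the recovery arrays of 122.51 µmol/L added for recovery, so their spread also differs from the main fit. The arrays of 1 time alone gave 0 at 6 h (limma, 3131 at an unadjusted p under 0.05), 555 at 12 h, 1 at 24 h, 118 at 48 h and 11253 at 72 h. Log2 concentration over exposed arrays, which drops the step from control, gave 3164, 54, 312, 261 and 658 for the trends of 3, 6, 12, 24 and 48 h. Removing the first residual component, which held 54.2% of the residual variance, gave 901, 9775, 114 and 5371 at 6, 12, 24 and 72 h and 4032 for the average. This step leaves the estimates unchanged and lowers only the spread, so higher counts follow from the step itself. Leaving out 24 and 48 h gave 1651 for the average and 3141 for the difference between times.

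Each array left out in turn, with the lone array left assumed to vary like other groups, gave these lowest and highest counts. For 122.51 µmol/L they were 7 and 28 at 3 h, 35 and 1968 at 6 h, 26 and 6962 at 12 h, 38 and 61 at 24 h, 362 and 674 at 48 h, and 1477 and 2535 at 72 h. For the trends they were 7 and 145 at 3 h, 88 and 2064 at 6 h, 43 and 7785 at 12 h, 79 and 149 at 24 h, 730 and 1567 at 48 h, and 2352 and 3808 at 72 h. For the lower concentrations at 48 h they were 25 and 61, 40 and 77, 126 and 446, and 198 and 3598, and at 72 h 33 and 70, 79 and 195, 122 and 201, and 363 and 537. They were 1457 and 4805 for the difference between times, 1393 and 5205 for the average, 262 and 781 for recovery against control, 9387 and 14994 against continuous exposure, and 261 and 472 for the 579 features shared by 48 and 72 h.

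Signs turned for 2 named transcripts. With the slide as a fixed block, which assumes a linear relation to concentration, ENSDART00000038200 in recovery was -0.32 and ENSDART00000019953 -0.16 against control, and with log2 concentration their 72 h trends were -0.24 and -0.15. These 4 values did not pass the threshold, and the cause of the turn was not tested. Signal over background limited little, with at least 93.2% of spots well above background. Every probe as its own feature is the main setting here, and the gene lists and their estimated correlation were not run.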

Other observations

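The sets of features below, their repeats under other settings and the slopes in recovery were chosen after the data were seen. Features that fell by more than 1 log2 unit in unexposed embryos between 27 and 30 hpf had lower medians at 122.51 µmol/L than in control after 12 h, a comparison whose count depends on single arrays. Of these 46 features, 30 fell and 1 rose at 122.51 µmol/L after 12 h, with a median of -1.77 (limma camera, adjusted p = 0.027 with an estimated correlation of 0.229, over 8 sets). The same 46 features had medians of -1.19 after quantile normalization and -1.57 in the deposited values, and of -1.6 to -1.77 without any 1 of the 4 arrays of 12 h (camera, unadjusted p of 0.000538 to 0.0118), although 4 instead of 30 fell past the threshold without control array 1. The 133 features that rose in controls over the same interval had a median of 0.17 (adjusted p = 0.744). Of the 3327 features that rose in controls between 48 and 72 hpf, 382 fell and 104 rose after 72 h of exposure (median -0.31, adjusted p = 0.27), and of the 1852 that fell, 491 fell and 54 rose (median -0.39, adjusted p = 0.376), so neither set passed. The 4 sets for the effects of 24 and 48 h did not pass either, with adjusted p of 0.759 to 0.967. The control arrays that define a set took no part in the effect it was tested on.

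Within the 6 recovery arrays alone, the slope on log2 concentration passed the threshold for 94 features (33 upwards, 61 downwards; 31.7% fell after quantile normalization and 57.9% in the deposited values, against 64.9%), and it differed from the slope over the continuous arrays of 72 h for 146 features. In 99 of these the continuous slope was the higher. This comparison does not need the recovery arrays to match the controls, but the concentrations of each series lie on 2 slides.

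At 24 h the difference between 122.51 µmol/L and control on 1 slide correlated with that on the other slide at -0.16 over all features. On the first residual component the exposed and control arrays scored -0.204 and -0.334 on 1 slide and 0.204 and 0.334 on the other. That component therefore enters the 2 differences with opposite signs and can lower this r. The r thus cannot decide whether the effect of 24 h was repeated on both slides. The component also separated arrays within 1 slide at 24 h. There the 2 arrays of 86.49 µmol/L scored 0.179 and -0.179, and those of 102.93 µmol/L -0.193 and 0.193.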
